A study of Mus musculus with 5 samples.

How the data were processed

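The data are 5 RNA-seq libraries of splenic CD4+CD25+ Tregs from mice on a high-fat diet, 2 WT and 3 KO. RNA was extracted with a column kit and depleted of ribosomal RNA, per the labels' protocols. Reads were trimmed with Trimmomatic 0.36 and aligned with STAR 2.5.2b to GRCm38, per the submitters' processing notes. The counting tool, the gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of near-identical copies, of overlapping genes and of antisense genes can therefore not be assigned with certainty.

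The authors deposited whole-number total counts per gene for 48440 genes. The authors also deposited RPKM values, which divide counts by gene length and depth, and TPM values, which sum to 1000000 in every library. A further deposited column named CPM sums to between 976872 and 1054093, so it holds a library factor beyond plain CPM, and it was not used. RPKM and TPM were used only to check the table. All tests start from the counts as deposited. Of the gene identifiers, 48058 were found in GENCODE M21, all on the same chromosome and 87.7% with the same start and end. Coordinates are those of the deposited table (GRCm38), and gene types were taken from GENCODE M21.

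Libraries were mapped to groups by their labels, and 0 columns were left unmatched. Total counts were 29598068 and 25622614 in WT replicates 1 and 2 and 26894939, 26122043 and 30521797 in KO replicates 1, 2 and 3. Libraries of the same group differed by more than sampling noise (chi-square per degree of freedom from 16.5 to 39.1, genes with at least 20 counts over both libraries), so none was taken for a second copy of another. This does not show that they come from separate animals. The biological coefficient of variation was 13.1%. Counting error is small beside this for most genes, but genes near 1 CPM have few counts and support only large differences.

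Genes were kept with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (estimateDisp, glmQLFit and glmQLFTest, genotype as the only term) in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over the 14460 genes kept, with a false discovery rate of 0.05. CPM values in the text are TMM-scaled, each mean ± is an SD over 2 WT or 3 KO libraries, and the SE of a log2 fold change is its size divided by the square root of the F statistic. Fold changes are the fitted log2 changes raised as powers of the base. For 26 gene lists, limma 3.58.1 camera with a preset correlation of 0.01 was run on log2 CPM (prior count 2), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Member counts are given over all genes tested and adjusted over the list alone.

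The design, the lists, the rule for named genes and all alternatives except pan-T cell scaling were fixed before the data were examined. The rule names Klf10, up to 12 genes with the largest rise and up to 12 with the largest fall among the called genes whose groups do not overlap and whose mean level is at or above the median, up to 4 called members of each list, and Foxp3, Il2ra, Ctla4, Tgfb1, Tgfb3, Klf2 and Klf11. All 12 rises and 1 fall met it. Of the 41 called genes, 28 lay below the median level and 3 have no name beyond a predicted gene number. Members named from lists without a called gene, and all other genes outside the rule, were chosen after their values were seen. Some members of the lists are not reported by name here.

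The alternatives were DESeq2 size factors, no filter and a stricter filter (a mean of 50 counts), a block for the replicate number, leaving out each library in turn, the DESeq2 1.42.0 Wald test, leaving out immunoglobulin, T cell receptor, haemoglobin, mitochondrial and ribosomal RNA genes, robust empirical Bayes, a false discovery rate of 0.10, and a minimum fold of 1.5. Scaling to the geometric mean of 14 pan-T cell genes was added after the data were seen, as were lists of pan-T cell, red pulp macrophage and erythroid genes used to describe the samples. The test was tried on simulated counts for the 14460 genes with 200 changed. The changed genes were drawn from those at or above the median level, and all genes were simulated independently. The test recovered 97% of genes changed by 1 on the log2 scale and 100% of those changed by 2. With them 26 unchanged genes were called, a larger share of the calls than the false discovery rate of 0.05. When no gene had changed, 0 were called. Recovery of changes below the median level, where 28 of the 41 called genes lie, was not tried. The recovery shares also hold for the simulated counts only. In the data, Alas2 and Car2, above the median level, were not called at log2 changes of 1.94 and 2.14 (edgeR adjusted p = 0.0635 for each). A gene that was not called may therefore still have changed by this much. In simulated lists the moved list passed (camera adjusted p = 2.35e-16) and 0 of 20 unmoved lists did. Genes in these lists were independent, whereas the 7 lists that passed in the data had estimated correlations from 0.18 to 0.92. The simulation can therefore not vouch for the camera p-values of those lists. The transcript identities come from blastn on GENCODE M21 transcripts. Python 3.11.15 with scipy 1.17.1 served for Fisher's exact tests.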

Results

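RNA was sequenced from regulatory T cells (Tregs), the CD4+CD25+ lymphocytes that restrain immune responses, enriched with magnetic beads from the spleens of C57B/6 mice fed a high-fat diet. There were 2 libraries from wild-type (WT) mice and 3 from mice without KLF10 in their CD4+ T cells (KO). KLF10 is a zinc-finger transcription factor of the Krüppel-like family, induced by TGF-β. The series concerns obesity and insulin resistance after loss of KLF10 in CD4+ T cells, and the comparison asks which transcripts of the Treg preparations differ between KO and WT. Total counts per library lay between 25622614 and 30521797, and 14460 genes had enough counts to be tested. The first principal component, with 52.1% of the variance, separated the WT from the KO libraries. Each library has its own code in the labels, which begins with A in WT and with B in KO, so whatever the letter marks goes with genotype. The labels do not say whether each code is a separate animal, so p-values measure the spread between these 5 libraries.

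Klf10 transcripts were lower in the KO libraries but were still present. Klf10 (ENSMUSG00000037465) is a protein-coding gene on the minus strand of chromosome 15, from 38294413 to 38300707 (GRCm38). It was measured at 22.3 ± 0.378 CPM (scaled counts per 1000000 reads; SD, n = 2) in WT and 12.5 ± 3.55 CPM (SD, n = 3) in KO, with 668 and 588 counts in the WT libraries and 408, 331 and 271 counts in the KO libraries. Every KO library lay below both WT libraries, with a log2 fold change of −0.84 (SE 0.22). The difference did not pass the false discovery rate of 0.05 over all genes (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.136), whereas the DESeq2 Wald test gave an adjusted p of 0.0195. The deleted part of the gene is not stated in the labels, so counts over the whole gene may include reads from parts that remain. Genes of other cell types were also measured in these preparations, so the remaining Klf10 counts cannot be assigned to T cells alone.

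**Figure D1:**
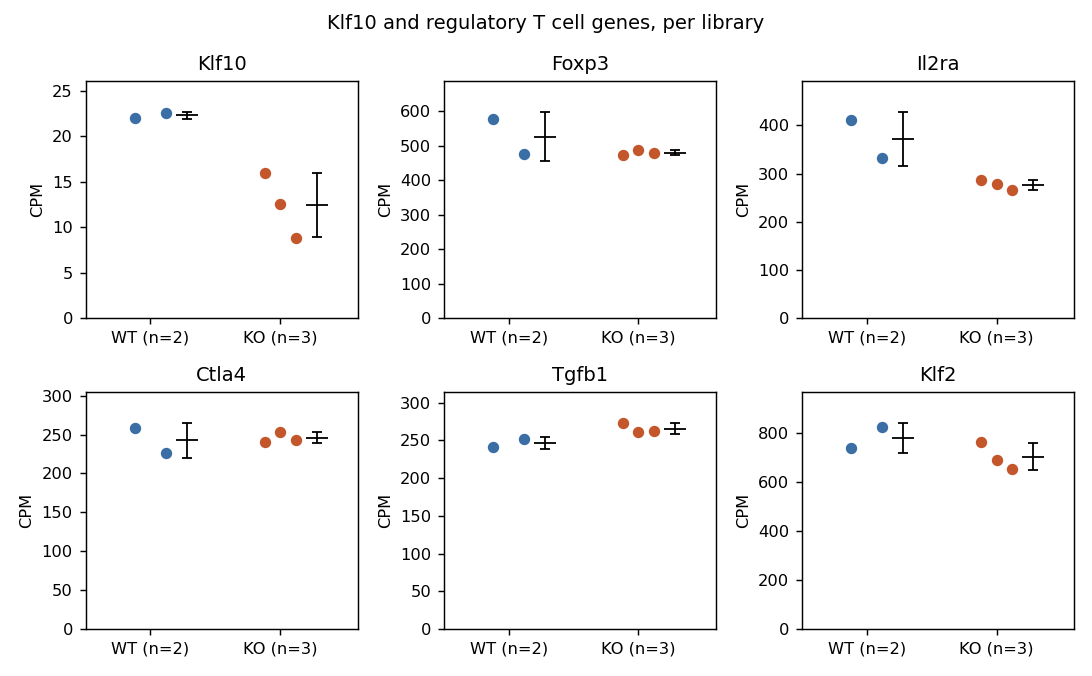
CPM (vertical axes, from 0) of Klf10 and 5 other genes in each of the 2 WT libraries (blue) and 3 KO libraries (orange), with the mean and SD of each group in black. Klf10 lies at 22.3 CPM in WT and 12.5 CPM in KO, Il2ra at 372 and 277 CPM, and the Foxp3 and Ctla4 libraries of the 2 groups overlap.

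Several genes of macrophages rose in the KO preparations. C1qc, a chain of the complement component C1q, rose 2.46-fold, from 43.6 ± 9.66 CPM (SD, n = 2) in WT to 107.6 ± 11.8 CPM (SD, n = 3) in KO. Adgre1, which encodes the macrophage surface protein F4/80, rose 2.19-fold from 28.6 ± 2.21 to 62.6 ± 7.91 CPM, and Cd68, a lysosomal membrane protein of phagocytes, rose 2.11-fold from 16.8 ± 0.916 to 35.4 ± 3.37 CPM. Ctsb, the lysosomal protease cathepsin B, rose 1.78-fold from 497 ± 18.3 to 883 ± 67.2 CPM. Also higher were the lysosomal phospholipase gene Pla2g15 (1.92-fold), the myeloid transcription factor gene Cebpa (1.78-fold), the syndecan gene Sdc3 (2.21-fold), the transglutaminase gene Tgm2 (1.84-fold), Plxnb2 (1.86-fold), Abhd4 (1.89-fold) and Arhgap19 (1.71-fold). Their edgeR adjusted p-values lay between 0.0142 for Plxnb2 and 0.0495 for Tgm2.

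In all, 33 genes rose and 8 fell among the 14460 tested (edgeR, false discovery rate of 0.05), and in all 41 the WT and KO libraries did not overlap. Over all genes the groups did not overlap in 35.0%, where chance gives 20%. An unadjusted p under 0.05 was reached by 1553 genes that were higher and 813 that were lower in KO. The number of calls rested on single libraries. Without WT replicate 2, KO replicate 2 or KO replicate 3 it was 3, 1 or 11, without WT replicate 1 it was 45 (21 up, 24 down), and without KO replicate 1 it was 334. Without KO replicate 2 there were 0 rises, and the 1 fall was Rpl30 (edgeR adjusted p = 0.0483). Without KO replicate 3 there were 5 rises and 6 falls. C1qc, Adgre1 and Cd68 were called in neither of these 2 settings (edgeR adjusted p from 0.0714 to 0.1231), but kept their calls without KO replicate 1. DESeq2 called 1022 genes, 812 up and 210 down. With the libraries scaled to 14 pan-T cell genes, a setting chosen after the data were seen that raised log2 changes by a median of 0.24, 1021 genes rose and 26 fell.

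Of the 8 genes that fell, Rpl30 was the most abundant. Rpl30, a protein of the large ribosomal subunit, fell from 787 ± 1.57 CPM (SD, n = 2) in WT to 279 ± 10.1 CPM (SD, n = 3) in KO, a log2 change of −1.50 (SE 0.06, edgeR adjusted p = 0.0020). Ribosomal protein genes have many near-identical pseudogene copies, so the share of reads given to Rpl30 itself is uncertain. Rpl30 lies on chromosome 15 at 34440505 to 34443640, 3.86 Mb from Klf10. Named here after their values were seen, 3 other genes that fell lie within 10 Mb of Klf10 as well. These were Polr2k, a small subunit shared by the RNA polymerases (log2 change −1.98, SE 0.11, edgeR adjusted p = 0.0045), Sema5a (−4.22, SE 0.32, edgeR adjusted p = 0.014) and Matn2 (−0.92, SE 0.11, edgeR adjusted p = 0.045). Ncald, 0.72 Mb from Klf10, rose from 19 and 10 counts in WT to 65, 75 and 96 counts in KO (log2 change 2.47, SE 0.30, edgeR adjusted p = 0.049). Of the 44 other genes tested within 10 Mb of Klf10, 5 were called, against 36 of 14415 elsewhere (Fisher's exact test, two-sided, p = 1.4e-07). The remaining genes that fell were Themis, described with the T cell genes, Col6a4 and Cpne4 on chromosome 9, and a predicted gene without a name.

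**Figure D2:**
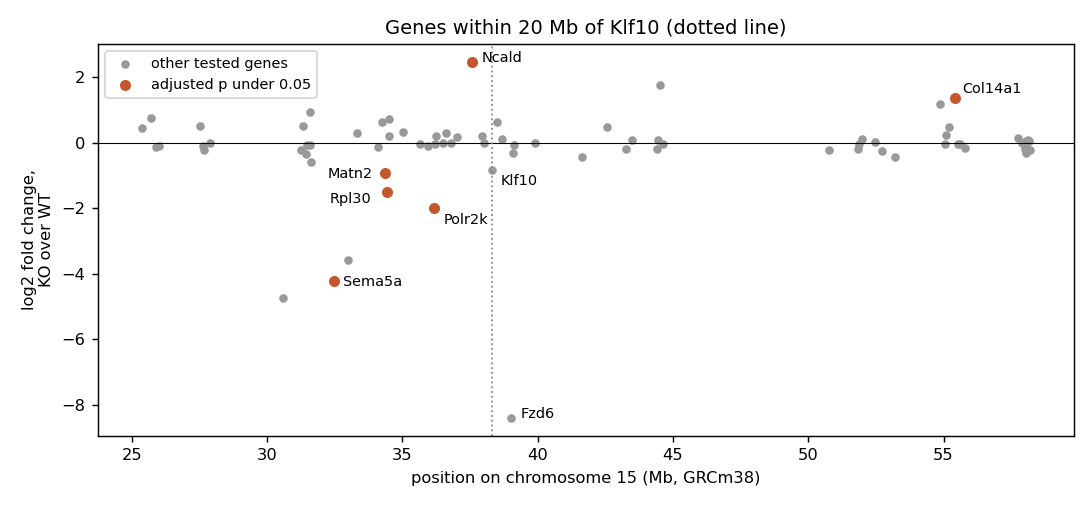
Log2 fold change of KO over WT (vertical axis) for every tested gene within 20 Mb of Klf10 against its position on chromosome 15 in Mb (horizontal axis, GRCm38), with the position of Klf10 as a dotted line. Genes past an adjusted p of 0.05 are orange and include Rpl30 (−1.50), Polr2k (−1.98), Sema5a (−4.22), Matn2 (−0.92) and Ncald (2.47).

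Eno1b showed the largest rise of the named genes, from 16 and 13 counts in the WT libraries to 4302, 7629 and 1977 counts in the KO libraries (0.513 ± 0.0204 CPM, SD, n = 2, against 174 ± 113 CPM, SD, n = 3, edgeR adjusted p = 0.045). It lies on chromosome 18 from 48045335 to 48048378 and is a copy of Eno1, the glycolytic enolase gene on chromosome 4, with 99.5% identity over 1652 of its 1791 transcript bases, so reads of these genes are uncertain. Eno1 was at 566 ± 27.8 CPM in WT and 362 ± 105 CPM in KO (edgeR adjusted p = 0.222). The sum of both genes was 567 ± 27.7 CPM in WT and 536 ± 14.01 CPM in KO, a log2 ratio of −0.08 with an SE of 0.05.

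**Figure D3:**
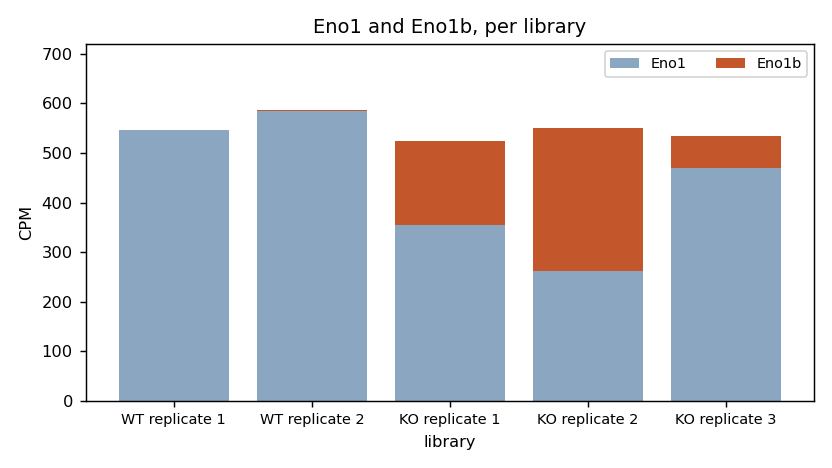
CPM (vertical axis, from 0) assigned to Eno1 (blue) and to its near-identical copy Eno1b (orange), stacked for each library. The stack is 547 and 586 CPM high in WT and 523, 551 and 535 CPM in KO, while the Eno1b part goes from under 1 CPM in WT to 168, 290 and 64.7 CPM in KO.

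Most markers of red cell precursors and of myeloid cells were higher in KO, and most genes of naive T cells were lower. All KO libraries lay above both WT libraries for 14 of 17 erythroid and platelet and 20 of 26 myeloid markers, and below both for 12 of 16 naive T cell genes. The haemoglobin genes took 1.72 ± 0.427% of the counts in WT (SD, n = 2) and 6.31 ± 1.68% in KO (SD, n = 3). Of 17 measured erythroid and platelet markers, 12 rose adjusted over the list alone, with 0 called over all genes by edgeR, and 11 by DESeq2 and with pan-T cell scaling (median log2 change 1.90, camera adjusted p = 3.3e-11, adjusted p = 0.9986 with an estimated correlation). Among them, Alas2, the first enzyme of haem synthesis in red cell precursors, went from 268 ± 55.0 to 1027 ± 347 CPM. Of 26 measured myeloid and dendritic cell markers, 3 rose over all genes tested by edgeR (Cd68, Adgre1 and C1qc), 16 by DESeq2, 17 with pan-T cell scaling and 18 adjusted over the list alone, with a median log2 change of 0.85 (camera adjusted p = 3.3e-11, adjusted p = 0.9986 with an estimated correlation). Naive and conventional T cell genes fell as a list of 16 (median log2 change −0.42, camera adjusted p = 7.7e-04, adjusted p = 0.9986 with an estimated correlation), with 1 up and 7 down by DESeq2. Themis, a signalling protein of the T cell receptor, fell over all genes tested, from 28.6 ± 2.58 to 16.9 ± 0.649 CPM (edgeR adjusted p = 0.049), and adjusted over the list alone 10 members fell, among them Tcf7 and Satb1, and 2 rose, one of them Il7r. With pan-T cell scaling the naive list passed as lower at a median of −0.18 (camera adjusted p = 8.2e-08), with log2 changes of −0.52 for Themis (edgeR adjusted p = 0.036), −0.11 for Tcf7 and −0.21 for Satb1 (edgeR adjusted p = 0.494 and 0.307).

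Markers of other cell types did not pass as lists with all libraries, and several passed in other settings. The 22 B cell markers had a median log2 change of 0.04 (camera adjusted p = 0.997), with 0 called over all genes or adjusted over the list alone, 1 at an unadjusted p under 0.05 and 0 by DESeq2. The B cell gene Ms4a1 (CD20) was at 409 ± 102 CPM in WT and 347 ± 15.8 CPM in KO. Without WT replicate 1 this list passed as lower in KO (camera adjusted p = 6.0e-04), and without WT replicate 2 it passed as higher (camera adjusted p = 4.7e-04). The 11 plasma cell markers had a median of −0.09 (camera adjusted p = 0.997) with 0 called by edgeR or DESeq2 and 1 at an unadjusted p under 0.05, and likewise passed as lower without WT replicate 1 (camera adjusted p = 0.0150) and as higher without WT replicate 2 (camera adjusted p = 0.0207). For the 16 neutrophil markers the median was 0.29 (camera adjusted p = 0.478), with 0 called by either tool and 1 at an unadjusted p under 0.05, and the list passed as higher without KO replicate 3 (camera adjusted p = 2.7e-08). Of 14 markers of CD8 T and natural killer cells, Fcgr3 rose and Eomes fell adjusted over the list alone, and 0 were called over all genes by edgeR (median −0.27, camera adjusted p = 0.178). By DESeq2, and by edgeR with pan-T cell scaling, these 2 were called over all genes. This list passed as lower without KO replicate 2 (camera adjusted p = 0.0064) and with pan-T cell scaling (0.0014). Fcgr3 is also a receptor of macrophages. Of 11 stromal and endothelial markers only Stab2, a scavenger receptor of sinusoidal endothelium, rose adjusted over the list alone (10.6 ± 1.55 to 21.5 ± 1.99 CPM, camera adjusted p = 0.233 for the list), and by DESeq2 and with pan-T cell scaling over all genes. The 4 measured sex-linked genes had 0 calls by edgeR or DESeq2 and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.616).

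**Figure D4:**
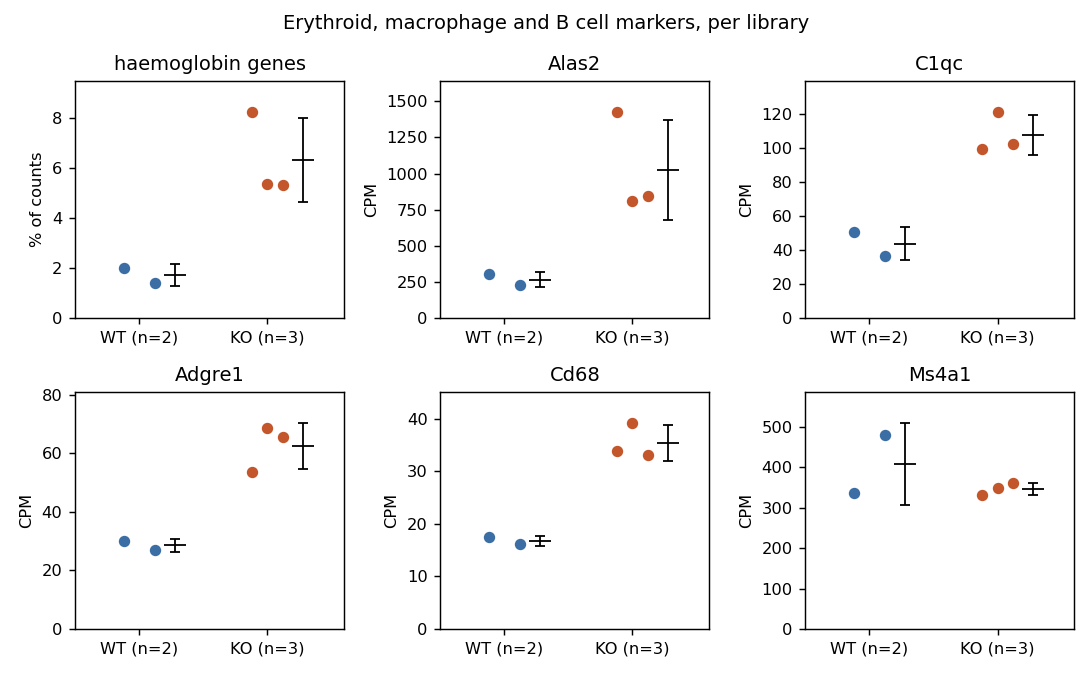
Share of counts from haemoglobin genes (percent, first panel) and CPM of an erythroid gene (Alas2), 3 macrophage genes (C1qc, Adgre1, Cd68) and a B cell gene (Ms4a1) in each of the 2 WT libraries (blue) and 3 KO libraries (orange), with the mean and SD of each group in black and axes from 0. The KO libraries lie above both WT libraries in every panel except Ms4a1, which is at 409 CPM in WT and 347 CPM in KO.

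The genes that define Tregs were expressed in both groups, and few of them differed. Foxp3, the lineage transcription factor, was at 527 ± 71.2 CPM in WT and 480 ± 7.72 CPM in KO (log2 change −0.13, SE 0.09, edgeR adjusted p = 0.524, and 0.11 with pan-T cell scaling). Ctla4, an inhibitory receptor, was at 242 ± 22.9 and 246 ± 7.11 CPM (edgeR adjusted p = 0.934). Il2ra, which encodes CD25, was lower in every KO library at 277 ± 10.2 CPM against 372 ± 56.1 CPM in WT (log2 change −0.42, SE 0.10), which did not pass over all genes (edgeR adjusted p = 0.104) but passed without the filter on low genes (edgeR adjusted p = 0.048) and by DESeq2 (adjusted p = 0.0089). Of the 32 Treg identity genes, 0 were called over all genes by edgeR, and 1 rose and 3 fell by DESeq2. Adjusted over the list alone, 4 fell and 1 rose. The genes that fell were Il2ra, Lrrc32 (GARP, the docking protein of latent TGF-β, 211 ± 36.1 to 142 ± 5.93 CPM), Ecm1 (65.3 ± 4.28 to 50.4 ± 1.77 CPM) and Socs2, and the gene that rose was Tigit, an inhibitory receptor (52.4 ± 2.17 to 73.7 ± 7.26 CPM). As a list they did not pass (median 0.0018, mean −0.02, test direction down, camera adjusted p = 0.974). These changes stand beside a median log2 change of −0.27 over the 14 pan-T cell genes, and with the libraries scaled to those genes Il2ra had a log2 change of −0.18 (SE 0.11), Lrrc32 of −0.32 (SE 0.11), Ecm1 of −0.13 and Socs2 of −0.10. Under that scaling Tigit was the only Treg identity gene called over all genes (log2 change 0.72, SE 0.14, edgeR adjusted p = 0.0152).

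TGF-β genes differed little. Tgfb1 was at 247 ± 7.88 CPM in WT and 266 ± 6.96 CPM in KO (edgeR adjusted p = 0.448), and Tgfb3 was near 1 CPM in both groups (1.07 ± 0.165 and 0.989 ± 0.198 CPM, edgeR adjusted p = 0.893), a level at which a modest difference could not be detected. Among the 27 measured genes of the TGF-β family 0 passed by edgeR, also adjusted over the list alone, 0 by DESeq2 and 1 at an unadjusted p under 0.05 (median −0.05, camera adjusted p = 0.611). With pan-T cell scaling the median was 0.19 and 1 gene, Bmpr1a, rose over all genes. Of 33 migration and homing genes, Ccr3 (2.5-fold) and Ccr8 (1.34-fold) rose and 3 fell adjusted over the list alone, among them S1pr1 and Xcl1, with 0 called over all genes by edgeR (2 up and 4 down by DESeq2). S1pr1, the receptor that guides lymphocytes out of lymphoid organs, went from 273 ± 0.463 to 212 ± 3.44 CPM. With pan-T cell scaling its log2 change was −0.13 (SE 0.12), while Ccr3 and Ccr8 passed over all genes (edgeR adjusted p = 0.0025 and 0.0140). The list as a whole was not called (median −0.08, mean 0.0079, test direction down, camera adjusted p = 0.478). Of 20 T helper effector genes 0 were called over all genes by edgeR (1 up and 1 down by DESeq2), and adjusted over the list alone the type 2 cytokine genes Il5 and Il13 fell and Maf rose. Il13 was at 4.39 and 12.2 CPM in the WT libraries and at 1.02, 2.01 and 0.295 CPM in the KO libraries (median of the list −0.13, camera adjusted p = 0.184). With pan-T cell scaling the list passed as lower relative to the other genes (camera adjusted p = 0.0069), at a median of 0.10, and over all genes Il5 and Il13 fell and 2 genes rose. Of 31 early genes of T cell activation 0 passed by edgeR, also adjusted over the list alone, 2 had an unadjusted p under 0.05 and 1 fell by DESeq2 (median 0.04, mean 0.0063, test direction down, camera adjusted p = 0.997).

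Transcripts of energy metabolism differed little between the groups. None of the 77 measured nuclear genes of oxidative phosphorylation passed by edgeR, also adjusted over the list alone, or by DESeq2, and 1 had an unadjusted p under 0.05. Their median log2 change was −0.03, with quartiles of −0.07 and 0.0079 (camera adjusted p = 0.184), and 0.21 with pan-T cell scaling. Without WT replicate 1 or KO replicate 2 this list passed as lower (camera adjusted p = 0.0013 and 0.0064). The 13 mitochondrially encoded genes were lower as a list (median −0.15, camera adjusted p = 0.0156, adjusted p = 0.9986 with an estimated correlation), with 0 single genes called by edgeR or DESeq2 and 0 at an unadjusted p under 0.05. Without WT replicate 1 the camera adjusted p of this list was 0.923, and with pan-T cell scaling its median was 0.10. Cholesterol and fatty acid synthesis genes were lower as a list of 28 by a small amount (median −0.09, camera adjusted p = 0.042, adjusted p = 0.9986 with an estimated correlation), with 0 single genes called by edgeR or DESeq2 and 1 at an unadjusted p under 0.05. This call was lost without KO replicate 3 (camera adjusted p = 0.716), WT replicate 1 (0.0536) or WT replicate 2 (0.145), and with pan-T cell scaling the median was 0.14.

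Glycolysis genes moved both ways without passing. Of the 25 measured, 0 passed by edgeR, also adjusted over the list alone, 1 rose by DESeq2, and 3 higher and 2 lower genes had an unadjusted p under 0.05 (median 0.02, camera adjusted p = 0.974). The monocarboxylate transporter gene Slc16a1 was at 37.0 ± 0.759 CPM in WT and 67.4 ± 19.8 CPM in KO, and the glucose transporter gene Slc2a3 at 121 ± 17.8 and 98.3 ± 1.17 CPM. Of 21 genes of the tricarboxylic acid cycle, Idh1 (1.47-fold) and Pcx (2.41-fold) rose adjusted over the list alone (median −0.03, mean 0.08, test direction up, camera adjusted p = 0.974). Of 29 fatty acid oxidation genes, Acsl1, which activates long-chain fatty acids, rose adjusted over the list alone from 31.7 ± 0.423 to 64.3 ± 15.2 CPM (median 0.00040, camera adjusted p = 0.974). Among 40 genes of PI3K-Akt-mTOR signalling, only Pik3cb rose adjusted over the list alone (1.47-fold), while the leukocyte subunit genes Pik3cd (547 ± 18.0 to 451 ± 27.5 CPM) and Pik3r5 (97.4 ± 2.30 to 81.0 ± 2.11 CPM) were lower in every KO library without passing by edgeR. Both passed by DESeq2 (adjusted p = 0.023 and 0.014), which called 2 members up and 3 down, and with pan-T cell scaling their log2 changes were −0.04 and −0.03. The median of that list was −0.01, its mean 0.10 and its test direction up (camera adjusted p = 0.974). Over all genes tested 0 members of these last 3 lists were called by edgeR, where pan-T cell scaling gave 2, 1 and 4 that rose, and 2 for glycolysis. DESeq2 called 2 tricarboxylic acid cycle genes and 1 fatty acid oxidation gene, all higher.

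Proliferation genes were higher in KO. Of 34 measured, 19 rose adjusted over the list alone, and over all genes 17 rose by DESeq2, 15 with pan-T cell scaling and 0 by edgeR, with a median log2 change of 0.49 (camera adjusted p = 1.2e-08, adjusted p = 0.9986 with an estimated correlation). Mki67, the marker of cycling cells, was at 223 and 249 CPM in the WT libraries and at 699, 403 and 435 CPM in the KO libraries, where haemoglobin genes took 2.03% and 1.42% of counts in WT and 8.25%, 5.36% and 5.32% in KO. Of 32 interferon response genes, 6 rose adjusted over the list alone, among them Rsad2 (viperin, 79.5 ± 17.6 to 384 ± 149 CPM), Isg15 (21.5 ± 4.45 to 75.4 ± 32.9 CPM) and Isg20 (60.2 ± 6.26 to 149 ± 41.6 CPM). In KO replicates 1, 2 and 3, Rsad2 was at 557, 301 and 295 CPM. Isg15 and Isg20 were also highest in KO replicate 1, which had the highest haemoglobin share. Over the whole list 19 estimates lay above 0 and 13 below. The interferon response list did not pass with all libraries (median 0.04, camera adjusted p = 0.184). It passed as higher without WT replicate 1 (0.0018) or KO replicate 3 (0.0307), and its direction was down without WT replicate 2 (0.603). By edgeR 0 members passed over all genes (8 rose with pan-T cell scaling, and by DESeq2 6 rose and 1 fell), and Oasl2, another interferon-induced gene, was at 7.18 ± 3.15 CPM in WT and 2.43 ± 1.53 CPM in KO. The 20 heat shock and stress genes had a median of 0.07 (camera adjusted p = 0.184), with 0 called by edgeR, also adjusted over the list alone, 3 higher ones at an unadjusted p under 0.05 and 1 by DESeq2, and the list passed as higher without KO replicate 3 (camera adjusted p = 0.0125). Of 18 other KLF and SP factors, only Klf1, the erythroid factor, rose adjusted over the list alone (11.9 ± 2.11 to 47.6 ± 19.1 CPM), and 0 were called over all genes by edgeR (median 0.02, camera adjusted p = 0.616). Klf1 was also the only one called by DESeq2 and with pan-T cell scaling. Klf2, a factor of T cell quiescence, was at 779 ± 61.5 CPM in WT and 702 ± 56.0 CPM in KO (edgeR adjusted p = 0.469), and Klf11, the nearest relative of Klf10, at 41.0 ± 7.14 and 45.8 ± 7.999 CPM (edgeR adjusted p = 0.693).

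Cytosolic ribosomal protein genes were lower in KO by a small and even amount. The 74 measured had a median log2 change of −0.23 with quartiles of −0.26 and −0.20 (camera adjusted p = 3.8e-25, adjusted p = 0.9986 with an estimated correlation). Adjusted over the list alone 65 fell, and over all genes tested only Rpl30 fell by edgeR, 52 by DESeq2, and Rpl30 and Rplp0 with pan-T cell scaling. The pan-T cell genes had a median of −0.27, and with the libraries scaled to them the median of the ribosomal protein genes was 0.0032, while the list still passed as lower relative to the other genes (camera adjusted p = 6.2e-12). Rplp0 stood apart from the rest at 2489 ± 381 CPM in WT and 1384 ± 213 CPM in KO, and Rpl29, which has near-identical copies, went the other way with 10047 and 731 counts in the WT libraries and 14554, 15797 and 17001 counts in the KO libraries.

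**Figure D5:**
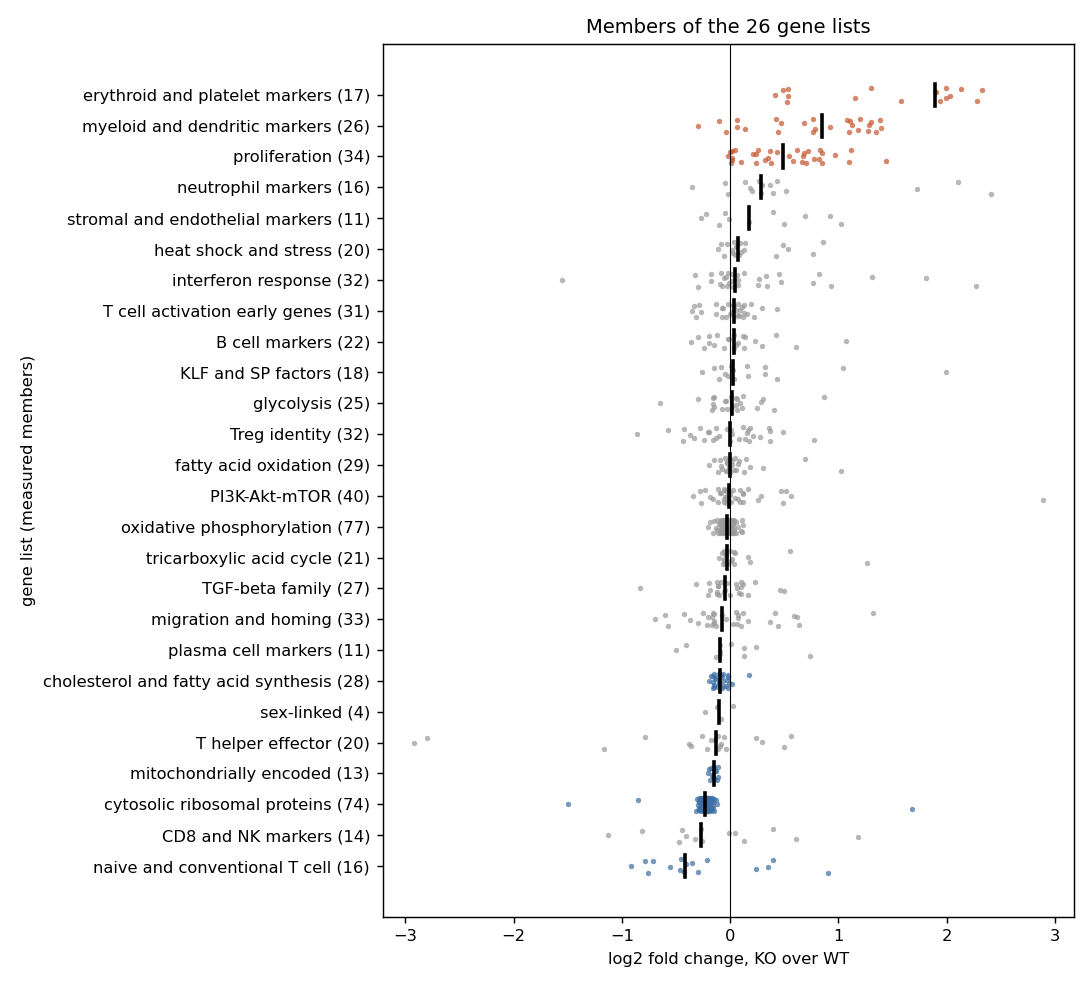
Log2 fold change of KO over WT (horizontal axis) for each measured member (points) of the 26 gene lists, with the median of each list as a black bar and the number of members in parentheses. Lists that passed camera with a preset correlation are orange (higher in KO) or blue (lower in KO), led by the erythroid list with a median of 1.90.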

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

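The alternatives were planned before the data were examined, except pan-T cell scaling. The 41 called genes became 33 with DESeq2 size factors, 49 with robust empirical Bayes, 589 without the filter on low genes, 23 with a mean of at least 50 counts, 1022 with the DESeq2 Wald test, 118 without immunoglobulin, T cell receptor, haemoglobin, mitochondrial and ribosomal RNA genes, 1047 with pan-T cell scaling, 579 at a false discovery rate of 0.10 and 7 with a minimum fold of 1.5 (1 up, 6 down). Leaving out each library in turn gave from 1 to 334 calls. The cause of these differences was not tested. Leaving out 1 of the 2 WT libraries assumes that the lone library varies like the KO libraries. Klf10 stayed lower under all alternatives, with log2 changes from −1.05 to −0.64 over the left-out libraries, and passed only with DESeq2 (log2 change −0.83, adjusted p = 0.0195, in a range of 0.0195 to 0.3545 over all alternatives). Of 182 alternatives for the other 14 called genes named by the rule, 110 kept the call, 72 lost it in the same direction and 0 turned, with most losses when a library was left out. The replicate numbers are shared by the groups, but same-numbered libraries did not deviate together (correlations of −0.0001 and 0.0625). With 2 WT libraries their deviations mirror each other, so this check cannot show that same-numbered libraries share only a number. A block for the replicate number gave 32 called genes, of which 6 were among the 41. It also gave 9 lists, among them T helper genes (lower, 0.0240), heat shock and interferon response (higher, both 0.0240) and neutrophil markers (higher, 2.9e-08). The 7 lists past camera were 6 to 9 in the other settings, 0 with an estimated correlation (1 list at an unadjusted p under 0.05) and 0 with fry (5 lists), while fry's mixed test, which asks for changes in either direction, passed 10. With an estimated correlation all 7 had an adjusted p of 0.9986. With fry it was 0.0604 for the ribosomal and the myeloid list, 0.180 for the naive T cell and the erythroid list, 0.476 for proliferation and 0.809 for the mitochondrial and the cholesterol list. The mitochondrial list also failed with the block (0.111), with pan-T cell scaling (0.263) and without 3 of the libraries in turn, with a range from 1.29e-06 to 0.923 over the left-out libraries. The cholesterol list failed with a mean of at least 50 counts (0.0581), the block (0.628), DESeq2 (0.0800), pan-T cell scaling (0.263) and without 3 of the libraries in turn, with a range from 0.0026 to 0.716. The B cell list turned to lower without WT replicate 1 (0.000604), in a range from 0.000469 to 0.942 over the left-out libraries, and the plasma cell list to higher without WT replicate 2 (0.0207), in a range from 0.0150 to 0.912. The other 19 lists passed in the same direction in 15 of 266 alternatives, over 8 lists. Robust empirical Bayes does not enter camera, so it has no value for lists. Depth limits genes near 1 CPM, such as Tgfb3.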

Other observations

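All tests in this part were chosen after the results were seen. Beyond the fixed lists, some genes of macrophages and red cells were higher in KO. Slc40a1, the iron exporter ferroportin, was at 57.7 CPM in WT and 127 CPM in KO, Cd5l, a macrophage protein, at 31.2 and 78.2 CPM, and Bpgm, a red cell enzyme, at 161 and 538 CPM. None of these 3 passed over all genes (edgeR adjusted p of 0.0598 for Cd5l, 0.0635 for Bpgm and 0.115 for Slc40a1), although the WT and KO libraries did not overlap for any of them.

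Some genes picked after their values were seen had few counts in 1 group. Gm13225 on chromosome 4 had 5 and 2 counts in WT and 550, 940 and 246 in KO, Zfp534 had 5 and 1 against 77, 119 and 39, and Arhgef16 had 6 and 3 against 227, 263 and 51. These 3 were not called (edgeR adjusted p-values from 0.0598 to 0.0775), and whether changes gather on this chromosome was not tested. On chromosome 9, Col6a4 (start 105989454) had 484 and 714 counts in WT and 0, 2 and 0 in KO. Cpne4 (start 104547286) had 243 and 292 against 30, 22 and 24 (both called). Near them lie Rpl29 (start 106429454) and Cacna2d2 (start 107399612), which was lower in KO without being called (log2 change −1.71, SE 0.23, edgeR adjusted p = 0.0598). Whether changes gather on chromosome 9 was not tested either. Gm10709, a near-identical copy of Rpl29 (99.5% over 422 bases), had 519 and 684 counts in WT and 7, 8 and 15 in KO. The sum of Rpl29 and Gm10709 was not similar between the groups, at 349 and 54.3 CPM in WT and 570, 601 and 557 CPM in KO.

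Macrophage and red cell precursor genes were higher in KO although the cells were enriched as CD4+CD25+, and all 19 measured red pulp macrophage genes lay higher in every KO library (median log2 change 1.20, Csf1r at 115 CPM in WT and 300 CPM in KO). A lower share of T cells with all other cell types raised alike is argued against, with all libraries, by the B cell markers. The median log2 change of myeloid markers exceeded theirs by 0.816. The B cell list moved lower without WT replicate 1 and higher without WT replicate 2, so this gap depends on the WT library. Haemoglobin RNA from lysed red cells alone is argued against by the 17 erythroid genes other than haemoglobin, with a median of 1.99 (8 of them are also in a fixed list). Of the red pulp macrophage genes outside the fixed lists and not called, 10 of 10 lay higher in every KO library, at a median log2 change of 1.17. Slc40a1 and Cd5l are among them. Over all genes, the groups lay apart in either direction in 35.0%. More red pulp macrophages in the KO preparations would give such a rise, but this list was written after the data were seen. The list can therefore not decide whether there were more of these macrophages. Whether the spleens held more of these cells, the bead enrichment kept more of them, or the samples were prepared apart stays open and untested, as does a change of these genes inside Tregs.

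Called genes crowded around Klf10 on chromosome 15. Regulation by KLF10 without regard to position is argued against as the account of this cluster, since 5 of 44 genes within 10 Mb were called (Fisher's exact p = 1.43e-07) and 0 of 14382 windows of this width centred on genes elsewhere held as many, with 4 as the highest. The 4 that fell had a median log2 change of −1.74, where the lowest pan-T cell gene was at −0.39. Being chosen as called favours large falls, but even the smallest, Matn2 at −0.92 (SE 0.11), lay below that gene. This argues against dilution of T cell RNA by other cells as the account of these falls. A segment of another strain carried along with the targeted allele may account for the cluster, since among genes with an unadjusted p of at least 0.001, which leaves out the called ones, 13 of 36 within 10 Mb had one under 0.05 against 2155 of 14226 elsewhere (Fisher's exact p = 0.00166, in a test that replaced one on the called genes themselves). Any effect on neighbours of the altered allele would give the same, and strain variants were not examined, so both stay open.

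Eno1b counts were higher and Eno1 counts lower in KO, with a similar sum. Reads of Eno1 assigned to its copy may account for the rise of Eno1b, since the log2 ratio of their summed CPM was −0.0786 (SE 0.05). Extra transcription of Eno1b on top of Eno1 is argued against, since the sum differed by −30.0 CPM (KO minus WT) where Eno1b gained 174 CPM. The reads themselves were not examined, so neither a move of reads between the copies nor its origin was seen directly. Eno1 starts at 150236721 on chromosome 4, and the picked genes Gm13225, Zfp534 and Arhgef16 lie around it (145510759 to 154301676). Like Eno1b, these picked genes had few counts in WT, most in KO replicate 2 and fewer in KO replicate 3 than in KO replicate 1. Of the genes between them, Gm21411 had the same order in KO (17, 24 and 12 counts). Angptl7 did not, with 4 and 4 counts in WT and 35, 74 and 46 in KO replicates 1, 2 and 3. Whether these changes share an origin was not tested.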
